A study of Mus musculus with 2 samples.

How the data were processed

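MicroRNA-seq libraries of RNA under 30 nt came from the hippocampus of female 5xFAD/CAST mice aged 8 to 10 months, with 2 biological replicates in 1 group, per the labels. The authors deposited 1 table of read counts per library, with 4 summary lines, 2202 miRNA genes and 3 columns of counts, and the counts were not normalized. The notes deposited with the tables name mm10 and the M21 gene annotation. The aligner, the counter and adapter trimming are not given in the sources used here. The 3 columns were read as counts without regard to strand, on one strand and on the other, and the summary lines as unmapped, multimapping, unassigned and ambiguous reads, from their names and values. The strand column with the larger total in both libraries was used as the sense strand, which held 93.4% and 91.9% of the counts of both strand columns (92.7% ± 1.03, SD, n = 2).

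Total depth, from the summary lines and the assigned counts, was 9962659 reads in replicate 1 and 12761689 in replicate 2. The 4 summary lines were kept out of library sizes and tests: unmapped reads were 26.5% and 18.1% of the total, multimapping reads 36.3% and 41.7%, and reads outside miRNA genes 5.72% and 5.91%, and in the sense column 0 reads were ambiguous. Multimapping reads stand in a line of their own, so the gene counts appear to hold reads of a single position, which would lower genes with identical copies. A gene-level count also adds both arms of a hairpin, so arms were not told apart. The reads of this strain were mapped to the mm10 reference, and the effect of strain variants was not tested.

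All 2202 identifiers matched the M21 annotation, which gave symbols, positions and overlapping genes. A further 5 of its 2207 miRNA genes, on unplaced scaffolds, were not used here. A gene counted as lying in an exon, UTR or intron of a host only if the host was on the same strand. Genes within 10000 bp on 1 strand formed a cluster. CPM was computed over the counts assigned to miRNA genes, and log2 levels with a pseudocount of 1. A gene was called detected at 10 counts in each library. The floor of a count of 0 was taken as 3 counts, and single-library shares have exact Clopper-Pearson 95% intervals.

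The 28 gene lists, the planned tests and the naming rule were fixed before the data were examined. The comparison of copies within 4 seed families was not among the planned tests. Of the listed symbols, 10 had no match. List levels were tested with 100000 permutations of gene labels, two-sided, on the difference of medians between a list and all other annotated genes, with Benjamini-Hochberg adjustment over 26 lists with at least 3 genes; the smallest p these permutations can give is 1e-05. Genes are not independent replicates. The endothelial and liver lists were too short to test. Lists were compared between libraries by the percentile of their median log2 ratio among 10000 random lists of like mean level, over members with at least 10 counts in either library. For each member, a random list drew 1 gene from the member itself and the 50 nearest in rank of level. At the ends of the ranking the end gene was repeated in place of missing neighbours, so it was drawn more often. Ratios are replicate 1 over replicate 2 after TMM scaling (edgeR 4.0.16 in R 4.3.3, factors 0.976 and 1.02), with 0.5 CPM added to both, and their intervals come from the exact binomial counts without that addition. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept alone. Each gene's 2 counts were tested with an exact binomial test, which takes counting error alone as its null. Copies were defined by symbols that differ in the number after the hyphen. Other computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

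Genes are named by a rule: the 20 most abundant, up to 4 leading members of each list, the 5 widest ratios in each direction with at least 100 counts, and a preset group that includes Mir124a and Mir9. Tested on simulated counts of 459 genes with 200 changed, the binomial test recovered 87% of 2-fold and 99% of 4-fold genes and called 2.32% of unchanged genes. These rates do not carry over to replicates that spread beyond counting error. Between the 2 libraries here, with a coefficient of variation of 0.385, the same test called 261 of 459 genes. The list test on 2202 genes called 4% of random lists and 100% of lists raised by 3 log2 units. For a true coefficient of variation of 0.447 over 459 genes, edgeR returned 0.462. Alternatives covered the count minimum, pseudocount, strand column, DESeq2 1.42.0 size factors, library totals, multi-copy genes and each replicate left out. No contrast between conditions was possible with 1 group.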

Results

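MicroRNAs (miRNAs) were sequenced from the hippocampus of adult female mice aged 8 to 10 months of a strain labelled 5xFAD/CAST. The 5xFAD transgenes carry human familial Alzheimer's disease mutations and produce amyloid plaques in the brain, and CAST is the usual short name of an inbred strain derived from wild Mus musculus castaneus. RNA under 30 nt was sequenced. The labels give 1 group of 2 biological replicates under a shared donor entry, and no second genotype, age or tissue. The data therefore give which miRNA genes had counts, at what level, and how far the 2 libraries lay apart. Multimapping reads, 36.3% and 41.7% of the total in replicates 1 and 2, stand outside the gene counts. Shares and ranks below may thus miss reads of miRNAs with several genomic copies. Replicate 1 held 9962659 reads and replicate 2 held 12761689. Of these, 3135960 and 4377622 were counted for a miRNA gene on its own strand, which was 31.5% (exact 95% binomial interval 31.4% to 31.5%) and 34.3% (34.3% to 34.3%) of the reads, or 32.9% ± 2.00 (SD, n = 2). Levels below are counts assigned to miRNA genes, scaled to the same total in each library (CPM), as mean ± SD with n = 2. A count of 0 allowed up to 0.957 CPM in replicate 1 and 0.685 CPM in replicate 2. The intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules.

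The let-7 family, which represses growth and stem cell genes and is abundant in differentiated tissue, supplied the largest share of the counts among the 28 gene lists. Its 12 genes, with Mir98 counted among them, held 37.0% ± 2.15 (SD, n = 2) of the counts. Mirlet7g was the most abundant gene at 120353 ± 4166 CPM, and Mirlet7b followed at 112307 ± 4909 CPM. Mir744 reached 85887 ± 5307 CPM and Mir139 reached 69078 ± 380 CPM. The 10 most abundant genes held 57.8% ± 2.28 of the counts, the top 20 held 71.0% ± 0.946, the top 50 held 88.1% ± 0.107 and the top 100 held 96.0% ± 0.0435. At least 10 counts in each library were reached by 384 of 2202 annotated genes, or 17.4%, and 1445 genes had 0 counts in both. The share of the top 10 was 59.4% in replicate 1 and 56.2% in replicate 2.

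The most abundant genes lay in varied positions, given here for mm10 with Ensembl identifiers as in the count tables. Mirlet7g (ENSMUSG00000065440.1) lies on chromosome 9 from 106178840 to 106178927 in an intron of Wdr82. Mirlet7b (ENSMUSG00000065564.1) lies on chromosome 15 from 85707319 to 85707403 in an exon of the long non-coding gene Lncppara. Mir744 (ENSMUSG00000076460.1) lies on chromosome 11 from 65734733 to 65734832 in an intron of Map2k4, which encodes a stress-activated kinase. Mir139 (ENSMUSG00000065446.1) lies on chromosome 7 from 101475376 to 101475443 in an intron of Pde2a, a cyclic nucleotide phosphodiesterase gene expressed in forebrain neurons. Mirlet7i (ENSMUSG00000065406.3) was at 56521 ± 5006 CPM and lies on chromosome 10 from 122985640 to 122985724, outside other genes on its strand. Mirlet7d (ENSMUSG00000065453.1) was at 36486 ± 17722 CPM and lies on chromosome 13 from 48536012 to 48536114 in an exon of the non-coding gene 6720427I07Rik. Mirlet7e (ENSMUSG00000105758.1) was at 32276 ± 1957 CPM and lies on chromosome 17 from 17830352 to 17830444 in an intron of Spaca6. Mir127 (ENSMUSG00000070076.2), an imprinted and maternally expressed miRNA, was at 24590 ± 432 CPM and lies on chromosome 12 from 109592846 to 109592915. Mir99a (ENSMUSG00000065530.1) was at 22178 ± 3726 CPM and lies on chromosome 16 from 77598936 to 77599000 in an intron of its host Mir99ahg. Mir29a (ENSMUSG00000065610.1) was at 18401 ± 5451 CPM and lies on chromosome 6 from 31062660 to 31062747.

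Ranks 11 to 20 held Mir126a, Mir132, Mir23b, Mir328, Mir151, Mir125a, Mir652, Mir330, Mir433 and Mir26b, from 17498 ± 7038 down to 10056 ± 1965 CPM. Neighbouring ranks among these differed by less than the SD between the libraries in several cases, such as Mir126a at 17498 ± 7038 against Mir132 at 17397 ± 6067 CPM. Mir652, in an intron of Tmem164 on the X chromosome, was at 10736 ± 30.5 CPM. Mirlet7e and Mir126a each share their position with an annotated miRNA gene on the other strand, and counted without regard to strand they fell to 0 and 0.172 CPM.

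**Figure D1:**
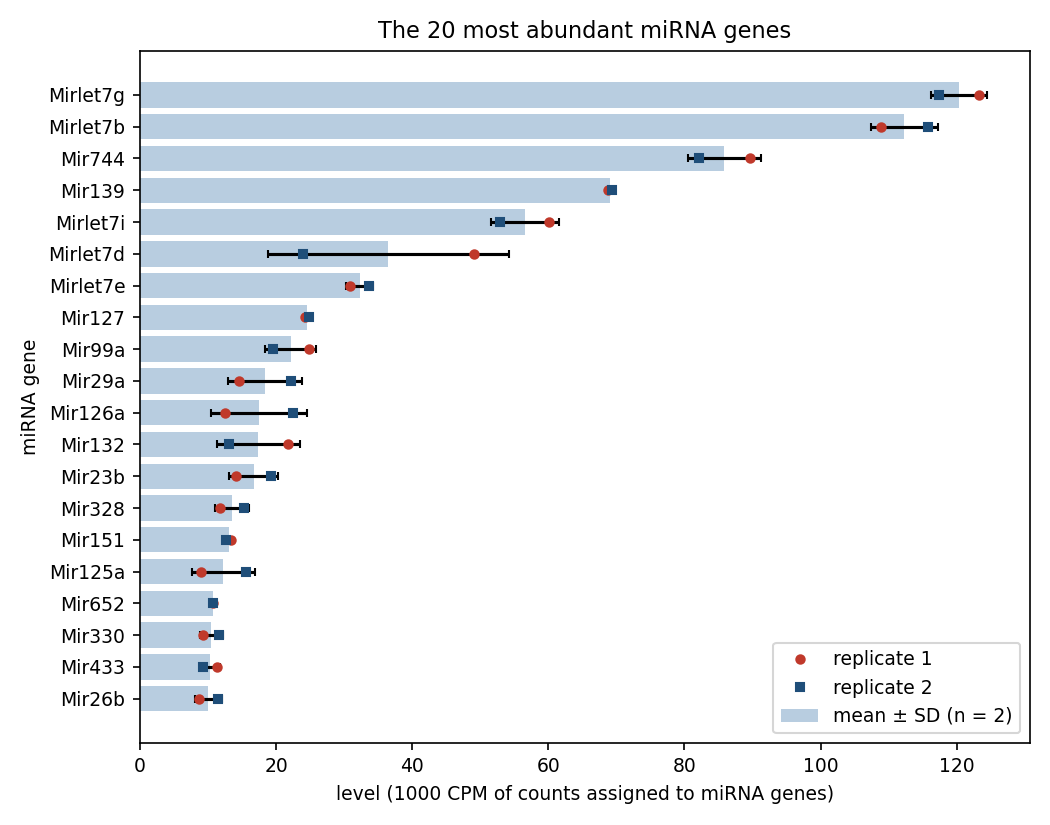
Level of the 20 most abundant miRNA genes, in units of 1000 CPM on a linear axis. Bars are the mean and whiskers the SD of the 2 libraries, and points are replicate 1 (circles) and replicate 2 (squares). Mirlet7g leads at 120353 CPM, and Mirlet7d has the widest whisker, at 17722 CPM.

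Neuronal miRNAs formed a large and broadly detected group. Of the 28 genes on the neuronal list, 24 were detected, and together they held 8.85% ± 0.250 of the counts (SD, n = 2). Mir127, Mir132, Mir433 and Mir128-1 led the list, with Mir128-1, which restrains neuronal excitability, at 6807 ± 3199 CPM. The median level of the list exceeded that of all other annotated genes by 9.06 on the log2(CPM + 1) scale (permutation test over genes, adjusted p = 5.2e-05). For this list and every other list tested, the median of the other genes was 0, as 1445 of the 2202 genes had no count. Such tests thus set a list mainly against genes without counts. The activity-regulated and synaptic list had 12 of 15 genes detected and held 3.26% ± 0.415, of which 9 genes shared with the neuronal list held 2.77% ± 0.479. Its leading gene Mir132, a target of the transcription factor CREB, was at 17397 ± 6067 CPM, and Mir212, from the same transcript, was at 287 ± 71.4 CPM. Mir137, Mir138-1 and Mir485, regulators of synapses and spines, were at 5706 ± 1342, 2170 ± 105 and 2075 ± 199 CPM. The median of that list was higher than that of other genes by 8.81 (permutation test, adjusted p = 5.2e-05). Among detected genes alone the difference was 3.55 for the neuronal list (permutation test, adjusted p = 0.00627). For the activity-regulated and synaptic list it was 3.19 and did not pass (adjusted p = 0.0887, same test).

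The Dlk1-Dio3 imprinted region on chromosome 12, whose miRNAs are expressed from the maternal allele, had the most detected genes of the 28 lists. Of its 56 listed genes between 109563692 and 109747960, 49 were detected, and they held 8.66% ± 0.301 of the counts. The neuronal list shares 9 of these genes, Mir127 and Mir433 among them, with 5.14% ± 0.144 of the counts, so the 2 shares overlap. Mir127, Mir433, Mir770 and Mir487b led, with Mir433 at 10275 ± 1432 CPM. Mir770, in an exon of the non-coding gene Meg3, was at 6801 ± 1247 CPM, and Mir487b at 5887 ± 1244 CPM. The list's median was 7.56 above that of other genes on the log2 scale (permutation test, adjusted p = 5.2e-05).

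**Figure D2:**
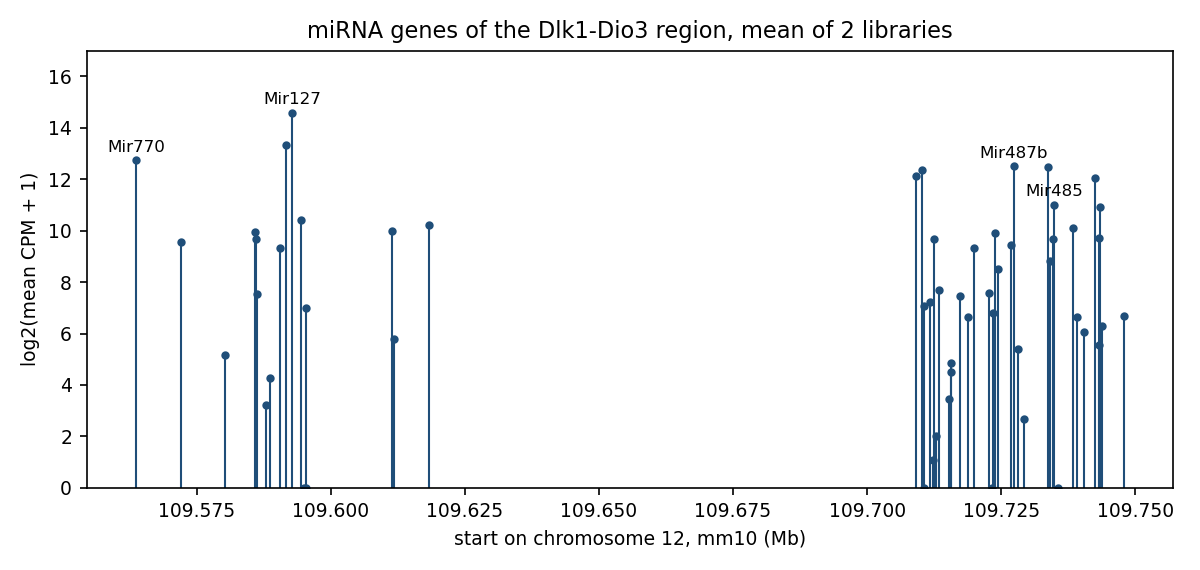
Levels of the 56 listed miRNA genes of the Dlk1-Dio3 region along chromosome 12 (mm10), as log2(mean CPM + 1) of the 2 libraries. Each stem is 1 gene at its start position, and Mir127 is the highest at 24590 CPM.

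Genes that the literature ties to amyloid and neuroinflammation ranged from 2.05 CPM for Mir9-2 to 18401 CPM for Mir29a, with no control genotype to set them against. Of 23 listed genes, 22 were detected, and the list held 6.30% ± 0.544 of the counts. It shares 4 genes with the miR-29 list, 5 with the microglia and myeloid list and 2 with the neuronal list, which held 2.04% ± 0.603, 1.04% ± 0.529 and 1.77% ± 0.614. Mir29a, whose targets include the beta-secretase gene Bace1, was at 18401 ± 5451 CPM. Mir22 was at 8419 ± 5125 CPM and Mir195a at 4790 ± 4717 CPM, and the SD of Mir195a was close to its mean. Mir146, a brake on Toll-like receptor signalling, was at 1526 ± 149 CPM. Mir155, induced in activated macrophages and microglia, was at 221 ± 19.0 CPM, and Mir142, a marker of blood-derived cells and microglia, at 241 ± 5.28 CPM. Mir223, abundant in neutrophils and other myeloid cells, was at 7.64 ± 0.468 CPM, from 25 and 32 counts. The list's median was 9.44 above that of other genes (permutation test, adjusted p = 5.2e-05). Among detected genes alone it was 2.84 above (permutation test, adjusted p = 0.0497).

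Among glial and vascular lists, the most abundant single marker was endothelial. Mir126a, in a non-coding exon of Egfl7 and a marker of endothelium, supplied all of that list's 1.75% ± 0.704, and Mir126b was at 0 on its own strand. The oligodendrocyte list held 0.674% ± 0.00796, with Mir219a-2 and Mir338, which promote myelination, at 3540 ± 343 and 3197 ± 423 CPM. Its other members Mir219a-1 and Mir3065 were at 4.99 ± 0.603 and 0.343 ± 0.485 CPM. The median of its 5 genes was 2.58 above that of other genes (permutation test, adjusted p = 0.0451), a call that ended without replicate 1 (adjusted p = 0.0507), without multi-copy genes (0.232) and in the unstranded counts (1). In the unstranded counts Mir219a-2 and Mir338, which share their positions with Mir219b and Mir3065 on the other strand, had 0 counts. The astrocyte-associated list had 5 of 5 genes detected and held 0.537% ± 0.280, led by Mir21a at 3431 ± 2468 CPM, with Mir181d at 1178 ± 107, Mir31 at 699 ± 449 and Mir193a at 51.5 ± 9.23 CPM (permutation test, adjusted p = 0.00345). The microglia and myeloid list had 5 of 8 genes detected and held 1.04% ± 0.529, most of it from Mir22, which is not restricted to these cells (adjusted p = 0.00345, permutation test). The smooth muscle and pericyte list held 0.752% ± 0.0924, with Mir143 at 7269 ± 872 and Mir145a at 248 ± 51.4 CPM (adjusted p = 0.0210, permutation test). The lymphoid list held 0.138% ± 0.00847, led by Mir150 at 797 ± 8.24 CPM (adjusted p = 0.0134, permutation test). Its other 2 genes, Mir181a-1 and Mir181b-1, are also on the miR-181 list, and Mir181a-1 on the activity-regulated and synaptic list as well. Among detected genes alone the oligodendrocyte, astrocyte-associated, microglia and myeloid, and lymphoid lists did not pass (permutation test, adjusted p = 0.147, 0.491, 0.700 and 0.621).

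The leading markers of blood, liver, muscle, fibroblasts and hindbrain ranged from 24.5 CPM for Mir206 to 253 CPM for Mir10a. Mir451a and Mir486 of red blood cells were at 37.6 ± 8.21 and 26.7 ± 3.93 CPM, and the erythroid list held 0.00743% ± 0.00058. Its median exceeded that of other genes (adjusted p = 0.0451, permutation test), but not without replicate 2 (adjusted p = 0.0674), with a pseudocount of 5 (0.067), by means (0.124) or in the unstranded counts (1). In the unstranded counts Mir451a and Mir486, which share their positions with Mir451b and Mir3107 on the other strand, had 0 counts. Mir122, the main miRNA of liver, was at 33.4 ± 7.07 CPM. In the striated muscle list 2 of 10 genes were detected, Mir206 at 24.5 ± 2.72 and Mir499 at 10.5 ± 3.96 CPM, while Mir1a-1 and Mir133a-1, both with further copies, had 0 counts (list, adjusted p = 0.121, permutation test). In the fibroblast and meninges list 1 of 4 genes was detected, Mir214 at 121 ± 6.46 CPM (adjusted p = 0.427, permutation test). Mir199a-1 and Mir199a-2, which are copies by symbol, had 0 counts. The hindbrain and spinal cord Hox list was represented by Mir10a at 253 ± 206 and Mir10b at 67.3 ± 50.9 CPM (adjusted p = 0.0705, and 0.0365 without multi-copy genes, permutation tests). None of the 14 pluripotency genes was detected, and the X-linked testis cluster had 1 of 22 detected, Mir547 at 6.71 ± 0.438 CPM. In the Mir466, Mir467, Mir669 and Mir297 families, many of whose copies lie in an intron of Sfmbt2, 8 of 81 genes were detected, led by Mir467d at 439 ± 59.3 CPM. These last 3 lists had a median of 0, as had all other genes (adjusted p = 1, permutation test), and by means the Sfmbt2 families lay below other genes (difference -0.86, adjusted p = 0.0190). Of these 81 genes 43 have further copies by symbol, so uncounted reads shared by copies may contribute to that lower mean.

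The leading genes of the epithelial, choroid plexus and endocrine lists were at 158, 1020 and 1772 CPM. The epithelial list held 0.0603% ± 0.0463 with 7 of 10 genes detected, led by Mir183 at 158 ± 159 and Mir200c at 107 ± 110 CPM (adjusted p = 0.00118, permutation test). The choroid plexus and ependyma list held 0.212% ± 0.135, with Mir34c at 1020 ± 1029 and Mir204, in an intron of Trpm3, at 946 ± 286 CPM (adjusted p = 0.00704, permutation test). The pancreas and pituitary list held 0.267% ± 0.0391, led by Mir7b at 1772 ± 131 and Mir375 at 716 ± 250 CPM (adjusted p = 0.00646, permutation test, and 0.0941 without multi-copy genes). Among annotated genes suspected to be fragments of rRNA or tRNA, 4 of 6 were detected with 0.0328% ± 0.00889 of the counts, led by Mir1983 at 240 ± 41.3 CPM (adjusted p = 0.0216, permutation test, and 0.0865 by means). Among detected genes alone none of these lists passed. The adjusted p was 0.812 for the epithelial, 0.807 for the choroid plexus, 0.655 for the pancreas and pituitary and 0.621 for the fragment list (permutation test).

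The miR-29, miR-30, miR-181 and miR-34 seed families, whose members share the bases that pair with targets, were detected in full. The miR-29 list held 2.04% ± 0.603, the miR-30 list 1.26% ± 0.231, led by Mir30d at 5831 ± 932 CPM, and the miR-181 list 0.446% ± 0.00500, led by Mir181b-2 at 1420 ± 175 CPM. The miR-34 list held 0.218% ± 0.136, led by Mir34a, a p53 target, at 1130 ± 312 CPM. In these 4 families all listed genes were detected (permutation tests of the levels, adjusted p = 0.00416 for miR-29, 0.000483 for miR-30 and for miR-181, and 0.00827 for miR-34). The miR-17-92 list and its paralogs held 0.266% ± 0.0136 with 8 of 15 detected, led by Mir93 at 1208 ± 180 CPM (adjusted p = 0.000585, permutation test). In all, 20 of 26 lists passed the test with a median above that of other annotated genes, and 0 passed it below. The comparison genes include the 1445 without a count, and among detected genes alone 15 of the 19 lists with enough genes had the higher median and 4 passed the test: the neuronal list (adjusted p = 0.00627), let-7 and miR-98 (0.00228), the Dlk1-Dio3 cluster (0.0279) and the amyloid and neuroinflammation list (0.0497), by the same permutation test.

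**Figure D3:**
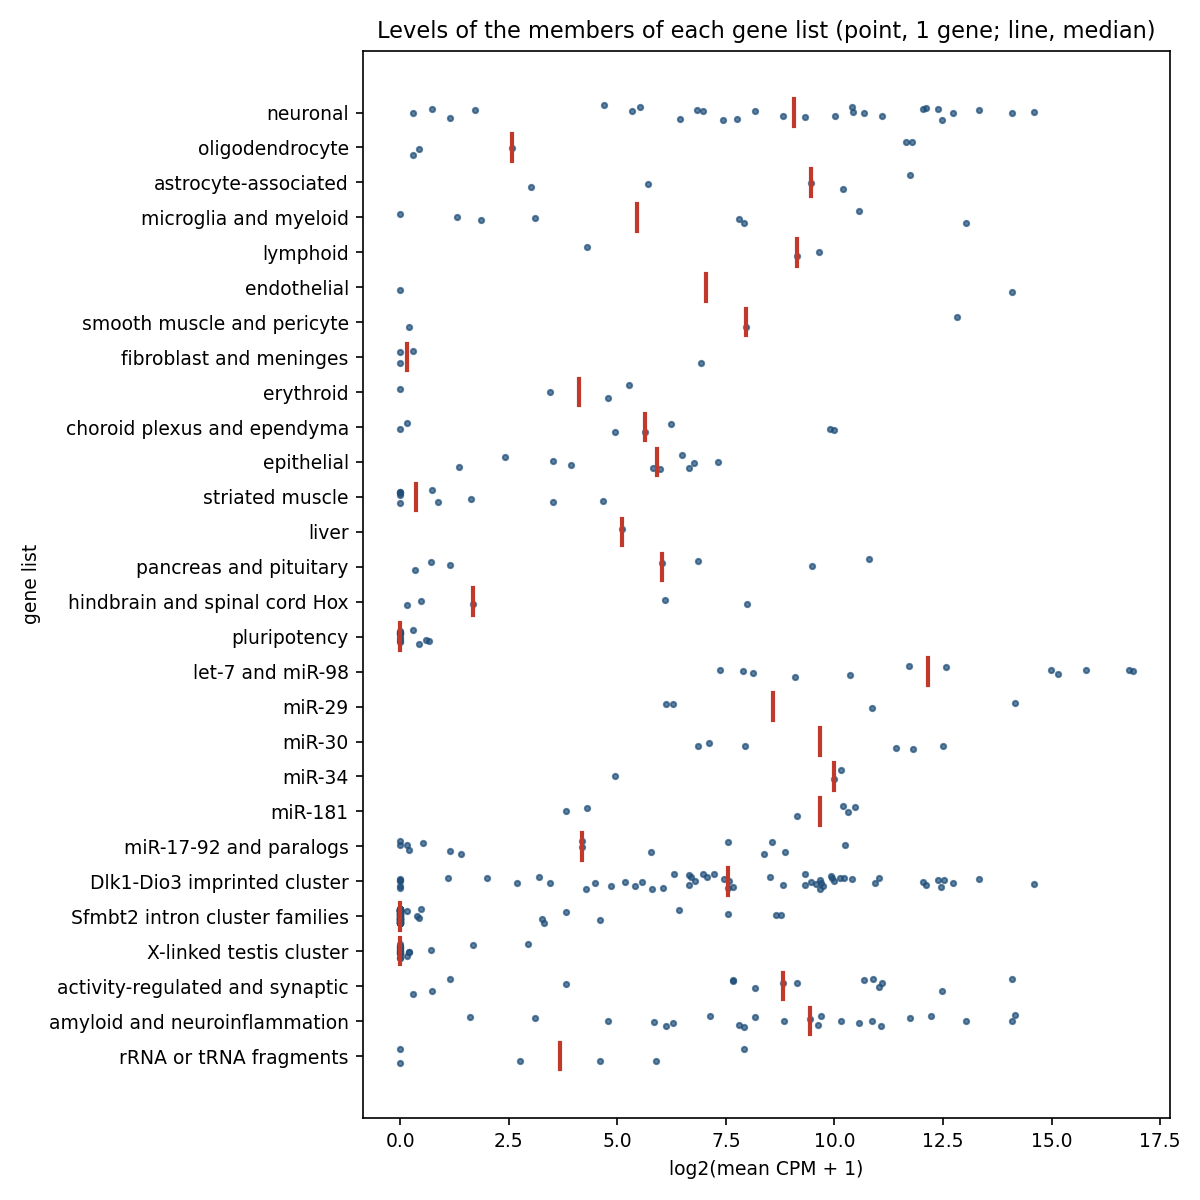
Level of each member of the 28 gene lists as log2(mean CPM + 1), 1 point per gene, with the list's median as a line. The median of the let-7 and miR-98 list is the highest, at 12.1, and the medians of the pluripotency, Sfmbt2 and X-linked testis lists are at 0.

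Members of 4 seed families with several genomic copies averaged lower than their single-copy relatives. Mir124a, the classic neuron-specific miRNA, has 3 genes: Mir124a-1 had 2 and 8 counts in replicates 1 and 2, Mir124a-2 had 0 and 2, and Mir124a-3 had 2 and 3. Mir9, another brain-enriched miRNA, was at 26.4 ± 1.73 CPM for Mir9-1, 2.05 ± 1.61 for Mir9-2 and 56.2 ± 3.53 for Mir9-3. In the let-7 family the 6 single-copy genes averaged 15.4 on the log2(CPM + 1) scale and the 6 multi-copy genes 9.09, a difference of 6.27 (exact permutation test, two-sided, p = 0.00216, the smallest this design allows). The differences were 6.31 in miR-29, 3.13 in miR-30 and 3.32 in miR-181, with exact permutation p of 0.333, 0.333 and 0.267, where the design allows no less than 0.333, 0.0667 and 0.0667. The highest miR-181 member was multi-copy, Mir181b-2 at 10.5, against 10.3 and 10.2 for the single-copy Mir181c and Mir181d. In miR-30 the single-copy Mir30b, at 6.87, lay below the multi-copy members. Over the 4 families together, with copies permuted within each family, the difference was 4.76 (exact permutation test, p = 0.000155). Multimapping reads stand apart from the genes in the tables, and how reads shared by copies were counted is not given in the sources used here, so levels of multi-copy genes are uncertain, Mir124a and Mir9 included. The comparison within families was not among the planned tests. In the planned comparison, across all 2064 single-copy and 138 multi-copy genes, both medians were 0 (difference 0, permutation test, p = 1). With the predicted genes of Gm symbols left out, the single-copy median was 0.59 higher (permutation test, p = 0.0286), and among detected genes alone the medians were 6.87 and 6.86 (permutation test, p = 1).

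**Figure D4:**
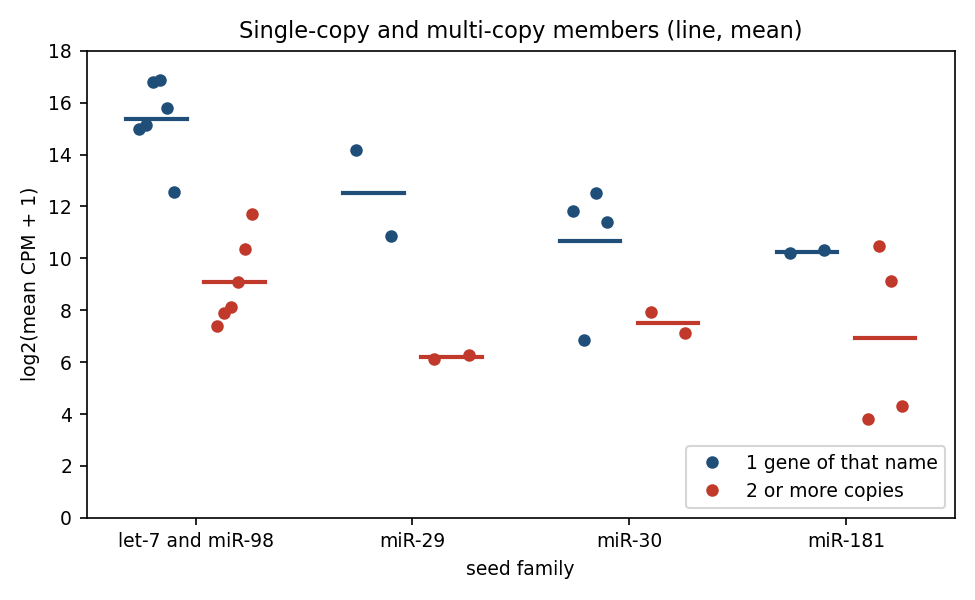
Levels of single-copy (blue, left) and multi-copy (red, right) members of 4 seed families as log2(mean CPM + 1), 1 point per gene, with lines at the means. The let-7 means are 15.4 and 9.09, and 1 single-copy gene of the miR-30 family lies below its multi-copy members. In the miR-181 family the multi-copy Mir181b-2 lies above the single-copy genes.

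The 2 libraries ranked the miRNAs alike, and most abundant genes were within 1.5-fold. Across 459 genes with at least 10 counts in either library, the Pearson correlation of log2(CPM + 1) was 0.975 and Spearman's rho 0.964, where genes are not independent replicates. Of 184 genes with at least 1000 counts over both libraries, 141 were within 1.5-fold and 18 differed by 2-fold or more. The biological coefficient of variation was 0.385. By an exact binomial test of these 2 libraries with Benjamini-Hochberg adjustment, 261 of 459 genes differed, 133 higher in replicate 1 and 128 in replicate 2. At 2-fold or more 75 of them did. These tests compare 2 libraries of 1 group and no condition. The labels give the replicates separate tissue samples under a shared donor entry, so p-values measure only the spread between these samples, which may be technical.

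Of the 21 lists compared between the libraries, the epithelial list had the widest median shift. Random lists draw genes singly, while log2 ratios of genes in 1 cluster were more alike than shuffled ones (SD 0.547 against 0.744). Percentiles of lists with clustered genes, the epithelial, miR-34 and Sfmbt2 lists among them, may thus be too extreme. All 9 epithelial genes tested were higher in replicate 1 (9 by the exact test over all genes, 9 adjusted over the list alone), with a median log2 ratio of 2.12 at percentile 100 of random lists matched on level. Mir200c, which with its relatives keeps epithelial identity, had 581 and 130 counts (log2 ratio 2.69, 95% interval 2.43 to 2.997), and Mir183, a sensory organ miRNA, had 847 and 199 (2.63, 2.42 to 2.87). All 5 choroid plexus and ependyma genes tested lay higher in replicate 1 (4 by the exact test, 5 adjusted over the list alone), with a median of 0.70 at percentile 98.7, led by Mir34c with 5478 and 1279 counts (log2 ratio 2.65). The miR-34 list, which shares Mir34b and Mir34c with it, had a median of 1.42 at percentile 99.2 (3 of 3 by the exact test and over the list alone).

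The let-7 and miR-98 list was higher in replicate 1 for 10 of 12 genes, with a median log2 ratio of 0.27 at percentile 98.4, and the Sfmbt2 families for 7 of 8 with 0.67 at percentile 99.1. By the exact test 12 and 7 of these differed, and 12 and 7 adjusted over the list alone. The miR-29 list was lower in replicate 1 for 3 of its 4 genes, with a median of -0.54 at percentile 2.45 (3 by the exact test, 3 adjusted over the list alone). For the most abundant genes the random lists drew Mirlet7g repeatedly, itself a let-7 gene with a log2 ratio of 0.14. The let-7 and miR-29 percentiles thus have an uneven reference and are uncertain. The let-7 and miR-29 percentiles fell inside the central 95% of random lists in the unstranded counts, at 96.5 and 2.71, and that of the Sfmbt2 families did with at least 100 counts, at 91.8. The other 15 of 21 lists compared lay inside it, among them the neuronal list at percentile 46.0 (19 of 25 genes by the exact test, 20 adjusted over the list alone) and the Dlk1-Dio3 cluster at 22.4 (41 of 51 and 41). The astrocyte-associated list was at percentile 79.3 (3 of 5 genes by the exact test, 3 adjusted over the list alone), and with at least 100 counts it moved outside, to 98.4 with a median of 0.68.

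Single genes with the widest ratios were chosen by a rule set beforehand, which itself required them to pass the exact binomial test. Mir26a-1, in an intron of Ctdspl on chromosome 9, had 592 counts in replicate 1 and 23 in replicate 2 (log2 ratio 5.11, 95% interval 4.64 to 5.91), and it has a second copy in the genome. Mir429 of the miR-200 family followed Mir200c, Mir34c and Mir183 at 2.04. In the other direction, Mir301, in an intron of Ska2 on chromosome 11, had 57 and 1538 counts (log2 ratio -4.17, interval -4.61 to -3.82). Mir195a was at -2.41, Mir1930 at -2.25, Mir148b at -2.02 and Mir99b at -1.92. Mir99b was the most abundant of these, with 8476 and 47027 counts, while Mirlet7e, which starts 164 bp away in the same cluster, had a log2 ratio of -0.05.

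**Figure D5:**
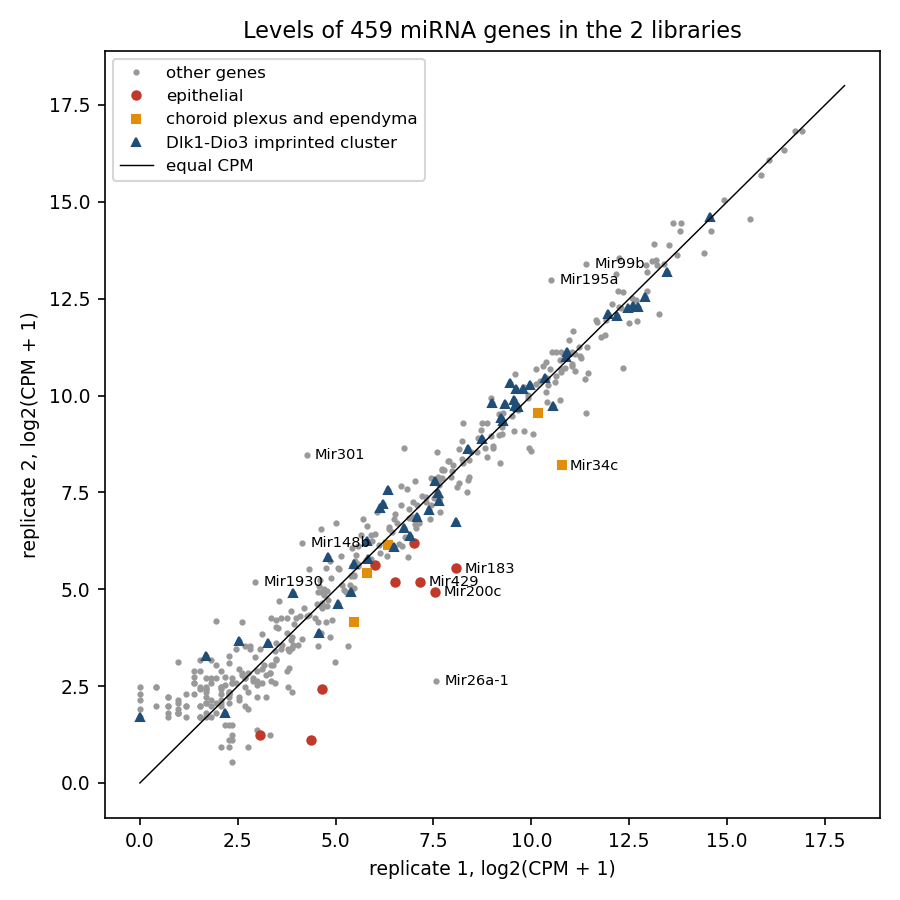
Level of 459 miRNA genes in replicate 1 (x axis) and replicate 2 (y axis), both as log2(CPM + 1), 1 point per gene, with the line of equal CPM. The epithelial genes (red circles) lie below the line, such as Mir200c with 581 counts in replicate 1 and 130 in replicate 2, and the 10 genes of widest ratio are named.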

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

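The tests of explanations in this part were chosen after the results were seen, on the same data. The labels give 1 group, so no biological difference between groups was tested.

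Signal outside the sense-strand gene counts was present in both libraries, above the floor of 3 counts. Reads that matched several positions numbered 3615399 in replicate 1 and 5325889 in replicate 2, more than the reads counted for genes by factors of 1.15 and 1.22. Counts on the strand opposite to the annotated gene numbered 221591 and 383401.

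Multi-copy members of the let-7, miR-29, miR-30 and miR-181 families averaged below their single-copy relatives, while over all detected genes the medians of both kinds differed by 0.01. Ambiguity between overlapping genes on 1 strand is argued against by the sense column, which held 0 ambiguous reads. For lower transcription of the multi-copy loci, members of both kinds were compared within clusters where both were detected. In 8 such clusters of these families the single-copy members were higher in 8, by 5.19 ± 2.20 (SD over clusters, log2 scale). The exact sign-flip permutation p was 0.00781, the smallest that 8 clusters allow, over genes of the pattern itself. These values argue against lower transcription for these clusters, if their hairpins share a transcript, which was not tested. In the 7 other such clusters the single-copy members were higher in 5, by 1.94 ± 3.12 (exact sign-flip permutation, p = 0.156), so lower transcription stays open there. Outside the 4 families, and without Gm symbols, the median of 899 genes that share no stretch of 20 nt with another annotated hairpin was 0.69 above that of 254 genes that do (permutation test, p = 0.00067). Detected were 31.4% and 26.4% of them, so these medians compare genes of few counts. The 254 genes include members of the Sfmbt2 families, such as Mir669o, which shares a stretch with 56 other genes. Of the 81 genes of these families 69 had 0 counts in both libraries. The comparison was not run without them, so how far the difference rests on these families is unknown. Another candidate explanation is that reads matching several copies, Mir124a and Mir9 included, were left out of the gene counts, and unequal processing of hairpins within a transcript was not tested.

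Epithelial miRNAs were higher in replicate 1. Hairpin GC content is argued against by a median ratio that was 2.18 after the GC trend was removed and 2.12 before, still at percentile 100 (SD over members 0.996 and 0.992). RNA of epithelial cells, in different amounts in the 2 tissue samples, stays open as a hypothesis: the separately fixed choroid plexus and ependyma list, which shares no gene with the epithelial list, was also shifted, at percentile 98.7. Its most abundant genes moved unequally, Mir34c by 2.65 and Mir204 by 0.70, and Mir200b, chosen after its values were seen, had a ratio of 0.46 beside 2.04 for its cluster neighbour Mir429. Which cells would be the source, and whether library preparation differed, was not tested.

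Counts on the opposite strand sat in few genes. Reads of an overlapping miRNA gene counted again for its partner on the other strand may be their source: 99.95% of them lay in 35 genes whose partner had the same sense count within 1%, such as Gm25927 with 244230 counts, opposite Mirlet7e. Antisense transcription of the hairpins is argued against as the main source, since the 274 counts left were 0.00365% of the sense counts. In the unstranded column 24 detected genes, 5 of them among the top 50, had 0 counts.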

How the results depend on the processing

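The definition of a copy by shared stretches of 20 nt and the comparisons without Gm symbols were chosen after seeing the data. The comparison of copies within 4 seed families was outside the plan. The planned definition from identical stretches in the genome was not run, since no genome sequence was used here. No paired analysis was possible because there is 1 group. The cause of the changes below was not tested, except where fewer genes or counts enter by construction.

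Detected genes numbered 604 with at least 1 count in each library. The share of the top 10 was 61.1% in the unstranded counts and 56.5% to 60.1% with either replicate left out. The replicate correlation was 0.964 and 0.982 with pseudocounts of 0.1 and 5, 0.989 with no filter and 0.962 with at least 100 counts, and the coefficient of variation was then 0.356. With a 2-fold minimum 75 genes differed. Among detected genes alone 15 of 19 lists were higher and 4 passed the test, and of the lists called before, the choroid plexus, epithelial and rRNA or tRNA fragment lists turned to -0.63, -0.43 and -1.64, none past the test (adjusted p = 0.807, 0.812 and 0.621). By means 1 list, the Sfmbt2 families, passed the test below other genes. The single-copy excess was 0.30 by shared stretches, 0.59 without Gm symbols and 0.73 with both (permutation p = 1e-05, 0.0286 and 0.00056). The genes that share a stretch include members of the Sfmbt2 families, and no comparison was run without these families. The share of reads counted was 30.3% in the unstranded counts, and the sense-strand share was 100% as a median over genes.

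The unstranded counts put Mirlet7e, Mir219a-2, Mir338, Mir30e, Mir142, Mir451a, Mir486, Mir9-1, Mir219a-1 and Mir1b at 0. Each of these shares its position with an annotated miRNA gene on the other strand. Ambiguous reads numbered 221479 in replicate 1 and 383239 in replicate 2 in that column, against 0 in the sense column. The other 48 alternatives of the main results stayed within their spread, within 1.5-fold or on their side of the threshold, and the 10 widest gene ratios kept their direction and call in all 60 of theirs. Of the levels of single lists under these alternatives, 198 kept their side of the threshold, 18 lost their call in the same direction, 2 lost it at a difference of 0, the 3 that turned lost it too, and 2 gained one. Counting error limits genes under 10 counts. The Mir124a copies are among them, and uncounted reads shared by copies may also lower their counts.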

Other observations

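The tests in this part were chosen after the data were seen, and several genes named here fall outside the naming rule and were chosen after their values were seen.

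Most hippocampal miRNA counts came from hairpins inside other genes. Introns of protein-coding genes held 154 of the 384 detected genes and 44.3% of the counts, and exons of long non-coding genes held 42 genes and 20.2%, Mirlet7b and Mirlet7d among them. Hairpins outside other genes on their strand numbered 101 and held 22.4%. Without genes of Gm symbols, 60.0% of the 70 hairpins in exons of long non-coding genes were detected, against 28.0% of the 357 outside other genes. Fisher's exact test, adjusted over 8 contexts, gave p = 5.12e-06. In introns of long non-coding genes the share was 52.7% of 55 (adjusted p = 0.00193 by the same test). Hairpins of 1 host transcript are not independent, which Fisher's test does not take into account. For introns of protein-coding genes the share was 29.1% of 515 (adjusted p = 0.761). Of the 1021 predicted genes with Gm symbols, 7 were detected, against 377 of 1181 others (Fisher's exact test, p = 1.31e-104). The highest of the 7 was Gm23450 at 1001 ± 53.0 CPM (SD, n = 2), on chromosome 7 from 3415066 to 3415156, in a coding exon of Cacng8, a gene for an AMPA receptor subunit partner.

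Hairpins of the same cluster differed widely in level. Mir132 exceeded Mir212, which starts 294 bp from it, 64.3-fold in replicate 1 and 55.4-fold in replicate 2. Mir143 exceeded Mir145a 27.7-fold and 31.4-fold, and Mir23b exceeded Mir27b 8.13-fold and 8.62-fold. Other pairs moved between the libraries: Mirlet7e exceeded Mir99b 11.4-fold and 3.13-fold, Mir195a exceeded Mir497 2.90-fold and 8.31-fold, and Mir451a exceeded Mir144 15.1-fold and 1.85-fold. Over 125 genes in 35 clusters with at least 100 counts, the SD of the replicate log2 ratio within clusters was 0.547, and 0.744 with ratios shuffled over the genes (permutation test, p = 0.0001, the smallest that 10000 shuffles give). Without the Dlk1-Dio3 genes these were 0.552 and 0.834, with the same p.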
